A study of Bradyrhizobium japonicum with 6 samples.

How the data were processed

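The samples were total RNA of B. japonicum USDA 110 and of an ntrC mutant in the same background, extracted with hot phenol per the labels' protocols. Per the same protocols, 10 ug of total RNA was copied into cDNA from random hexamers, and 4 ug of cDNA was labelled with Cy3 or Cy5. The labels give 3 biological replicates per strain, with a dye swap of each hybridization, on 6 arrays. An array therefore compares both strains, and a group here is a dye orientation with 3 arrays.

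The deposited values are log ratios between the dyes of each array and were read as log2. The scanner, the normalization, the log base and the numerator are not given in the sources used here. Both signs occur, array medians lie between -0.01 and 0.02, and array SDs lie between 0.50 and 0.60. On a log10 scale these SDs would put a typical probe several-fold apart between the dyes of an array, so log10 was set aside. A natural log (1.44 log2 units per unit) was not ruled out. Channel 1 (Cy3) was taken as the numerator, from the order in the sample titles, and arrays with the mutant in Cy5 were turned. The direction is therefore called likely. No centring or scaling was added, and no spot intensities were used, so signal over background is unknown. Any effect of the authors' normalization on the ratios remains in the values.

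The table has 8480 probe rows and 6 columns. A platform annotation paired 8462 rows with 1 gene symbol, none with several and 18 with no symbol, and in 1469 rows the symbol differs from the locus tag. It holds no product names, coordinates or genome build, so genes are given by symbol and locus tag. Order along the genome and strand were read from the locus tags by their naming convention. The 680 probes with a missing value were left out of the main test.

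Ratios turned to mutant over wild type were averaged over the 2 arrays of a replicate number, which cancels a dye effect, and the 3 replicate values were tested against 0 with lmFit and eBayes of limma 3.58.1 in R 4.3.3. P-values were adjusted by Benjamini-Hochberg over all probes, with a threshold of 0.05. Errors are SDs of the 3 replicate values. Probes of different IDs for 1 gene were kept apart. Whether the numbers pair the arrays was checked by the correlation of deviations from the orientation means: it was 0.55, 0.52 and 0.51 for same-numbered arrays. It was nearly as high, at 0.35, 0.48 and 0.40, for A2 with B1, A3 with B2 and A1 with B3, where A has the mutant in Cy3 and B the mutant in Cy5, so the numbers do not stand apart from these. It was -0.97, -0.91 and -0.94 for A1 with B2, A2 with B3 and A3 with B1. Deviations sum to 0 over the 3 arrays of an orientation, so these negative values force the others to be positive on average. The positive values therefore do not show that the numbers pair the arrays. The labels pair the arrays by stating a dye swap of each hybridization, and every SD with n = 3 and every main p-value rests on that pairing.

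Before the data were examined, 18 gene lists were fixed by symbol, locus tag or product words. Without product names the product words matched nothing, so the lists of amino acid transport and transposases were empty and 16 lists were tested. Each was tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted by Benjamini-Hochberg over the lists. The named genes follow a rule fixed at the same time. It takes the genes of the ntr region and glnA, glnII, glnB, glnK, amtB, gltB and gltD, whatever their result. It also takes the 12 highest and 12 lowest means among probes that passed with 1 sign in all 3 replicates, and up to 4 members with the smallest p in each list, not all of which are printed. Names outside the rule are stated to be so, except nolA, rhcU, rhcC1 and rhcN, which complete the counts of their lists. Neighbouring genes were compared by Pearson correlation with 10000 permutations. Plots were drawn with matplotlib 3.10.9.

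The tests were tried on simulated data: 5 simulations of 7800 probes with 200 changed, which took their correlations between arrays from the real arrays and therefore assume the loop structure described among the closing observations. With moderated variances per probe, the main fit recovered 0, 68.0, 100 and 100% of changes of 0.5, 1, 1.5 and 2 log2 units. Of its calls 0% were false. The loop fit, which has the structure that was simulated, recovered 87.2, 100, 100 and 100%, and 4.44% of its calls were false. A probe that did not pass the main fit may thus still have changed. A first version used raw variances per probe. In it the main fit recovered 0, 0, 36.0 and 64.4%, and the loop fit 41.6, 88.4, 97.2 and 99.6%. The second version was made after that result was seen, because raw variances hold their own sampling noise.

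Alternatives covered centring, scaling and quantile normalization, the replicate block with and without a dye term, single dye orientations, missing values, a limit on the difference between swapped arrays, robust variances, treat with a minimum fold of 1.2, other thresholds, averaged probes, the turned sign and leaving out each replicate. A fit to a loop of 3 batches and another pairing of arrays were added after seeing the data.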

Results

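Transcript levels of the soybean symbiont Bradyrhizobium japonicum USDA 110 were compared between the wild type and an ntrC mutant on 6 two-colour arrays. NtrC is the response regulator of the nitrogen regulatory (Ntr) 2-component system, which controls genes of nitrogen assimilation in many proteobacteria. Both strains were grown with 10 mM ammonium and 10 mM glutamate, a nitrogen-rich medium, and were harvested at an OD600 between 0.4 and 0.6. The labels give 3 biological replicates. Each replicate number has 1 array with the mutant in Cy3 and 1 array with the mutant in Cy5. Of the 8480 probes in the table, 7800 had a value on all 6 arrays. The number missing per array ran from 113 to 550. The table holds ratios and no spot intensities. The number of arrays limits the precision.

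Ratios are given as mutant over wild type. This direction is likely rather than settled, because the table does not name the numerator. It rests on the order of the channels in the sample titles, and if the order is the other way every sign below turns. Values are read as log2. If they are natural logs, each log2 value grows by a factor of 1.44 and the folds grow with it. Median log ratios of the 6 arrays lay between -0.01 and 0.02.

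Same-numbered arrays of opposite dye orientation had correlations across probes of -0.66, -0.55 and -0.59 for replicates 1, 2 and 3. With A for the mutant in Cy3 and B for the mutant in Cy5, 3 differently numbered pairs of opposite orientation were similar, at -0.58 for A1 and B3, -0.48 for A2 and B1 and -0.53 for A3 and B2. Arrays of the same orientation had correlations between -0.13 and 0.06. Arrays A1 and B2, A2 and B3, and A3 and B1 had positive correlations of 0.41, 0.47 and 0.33 although their orientations are opposite. Probes are not independent replicates in these values.

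**Figure D1:**
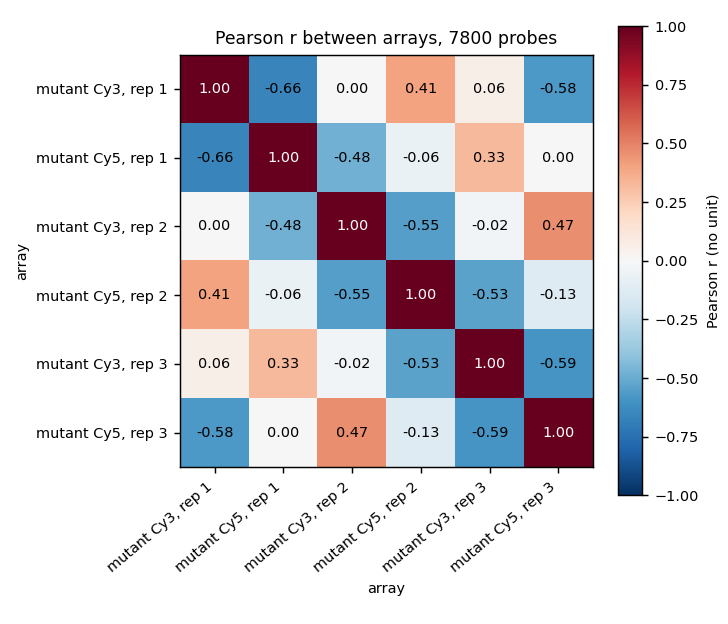
Pearson correlation (no unit) of the deposited log ratios across 7800 probes for each pair of the 6 arrays, which are named by the dye of the mutant and the replicate number. Same-numbered arrays lie between -0.66 and -0.55, 3 differently numbered pairs of opposite orientation between -0.58 and -0.48, and the other 3 such pairs between 0.33 and 0.47.

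The targeted gene was examined first. The ntrC probe (blr4488) had a mean log2 ratio of -0.68 ± 0.23 (SD, n = 3), 1.60-fold lower in the mutant, which did not pass the test (limma, adjusted p = 0.527). Its 3 replicate values were -0.55, -0.95 and -0.54. The deposited ratio of this probe was negative on all 6 arrays, in both orientations, though only -0.002 on B3. With the mutant in Cy3 alone its log2 ratio was -1.63, and with the mutant in Cy5 alone it was 0.27. The labels do not say which part of ntrC is altered, so a probe outside that part would check nothing.

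None of the other genes of the ntr region passed. The sensor kinase gene ntrY (blr4489) stood at -0.78 ± 0.20 (SD, n = 3; limma, adjusted p = 0.236), nifR (blr4486) at -0.61 ± 0.43, ntrB (blr4487) at -0.26 ± 0.34 and ntrX (blr4490) at 0.15 ± 0.42. Of the 5 probes of this list, 2 fell when adjusted over the list alone, ntrY and the targeted ntrC, and the list median was -0.61. The ratio of ntrC differed in sign between the dye orientations, so this count and the list test below rest partly on that probe. The list was lower than other probes with the preset correlation of camera (adjusted p = 0.0015). The correlation estimated among its members was 0.21, above the preset 0.01, so that p-value may be too small. The call was lost with an estimated correlation (camera, adjusted p = 0.463). With 3 values per probe that version has few degrees of freedom, and none of the 16 lists passed by it (smallest adjusted p = 0.268). A call lost there says little about a single list.

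Of 7800 probes, 123 passed (limma, adjusted p under 0.05), and 105 of these were higher and 18 lower in the mutant. Of the 123, 116 changed at least 2-fold and 116 had the same sign on all 6 arrays. At any p, 117 probes changed at least 2-fold, and 116 of them passed, so the test acted much like a fold limit. With 58.7 prior degrees of freedom, limma gave most weight to a spread shared across probes. A small p therefore says little about the agreement of a probe's own 3 replicates. The highest means were those of bkdA1 (blr6331), blr5962 and bll6809, and the lowest was that of fer3 (bsr1750), a ferredoxin gene.

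The highest mean was that of bkdA1 (blr6331), which encodes a subunit of the branched-chain 2-oxo acid dehydrogenase. It was 9.88-fold higher, at a log2 ratio of 3.30 ± 0.83 (SD, n = 3; limma, adjusted p = 1.77e-13), and was higher on 6 of 6 arrays. The gene bkdB (blr6333) of the same complex was 7.65-fold higher, at 2.94 ± 0.65. Among genes that the annotation gives only by locus tag, blr5962 was 9.76-fold higher, at 3.29 ± 0.92, and bll6809 was 8.89-fold higher, at 3.15 ± 0.64. Then came blr5963 (2.69 ± 1.40), bll5338 (2.55 ± 0.55), blr5966 (2.42 ± 0.86), bll1804 (2.38 ± 0.26), blr1649 (2.28 ± 0.07), bsr4726 (2.28 ± 1.39) and bll1846 (2.17 ± 0.04). The twelfth was icfA (bll2065), a symbol used for carbonic anhydrase, at 2.13 ± 0.59, 4.38-fold higher. All 12 passed.

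Among the 18 lower probes, fer3 (bsr1750) was 12.2-fold lower, at -3.61 ± 0.43 (SD, n = 3; limma, adjusted p = 1.49e-15), and was lower on 6 of 6 arrays. It was followed by blr7829 at -2.36 ± 1.36, which was 5.14-fold lower. The next were bll4376 (-1.62 ± 0.36), bll7927 (-1.52 ± 1.19), bll4057 (-1.50 ± 1.02), dht (blr7615, -1.36 ± 0.50), blr7816 (-1.35 ± 1.35) and bll7538 (-1.32 ± 0.75). The probes blr7172 (-1.28 ± 0.32), bll4168 (-1.27 ± 0.32), bll2373 (-1.24 ± 0.21) and blr2506 (-1.19 ± 0.23) completed the 12 with the lowest means among probes with 1 sign in all 3 replicates. The probe of leuA (bll6435), which lacked 1 sign in all 3, passed at -1.29 ± 1.28 and was named after its value was seen. It did not pass with the replicate block (limma, adjusted p = 0.509). With the replicate block, bll7927, bll4057, blr7816 and bll7538 did not pass (limma, adjusted p = 0.165, 0.0873, 0.443 and 0.213), and with a fit to a loop of 3 batches bll7927, bll4057 and blr7816 did not (adjusted p = 0.0781, 0.0907 and 0.0913). The SD of blr7816 was as large as its mean, and its 3 replicate values were -2.90, -0.65 and -0.48.

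**Figure D2:**
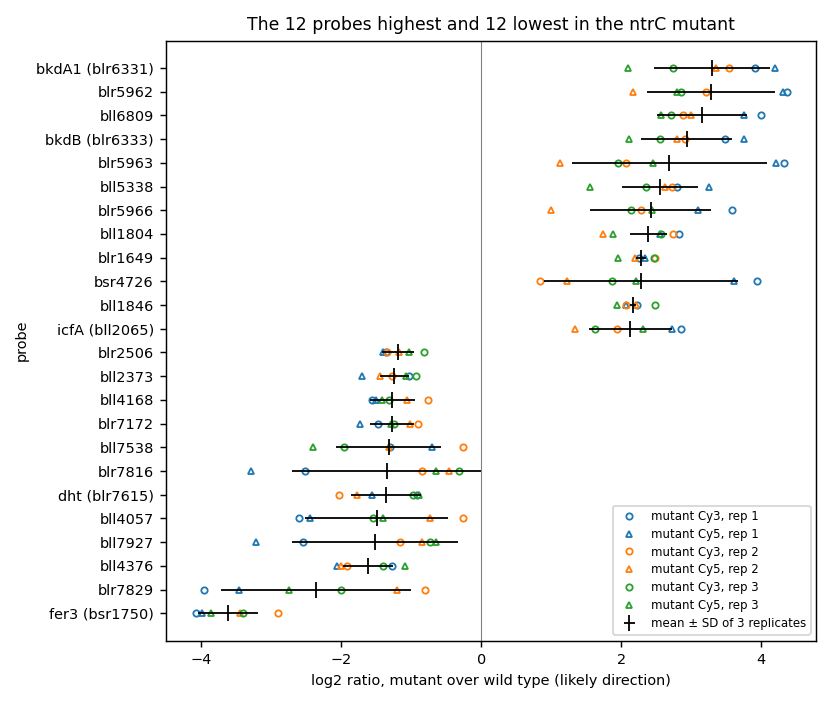
Log2 ratio of mutant over wild type for the 12 highest and 12 lowest probes that passed with 1 sign in all 3 replicates. Open symbols are the 6 arrays, with circles for the mutant in Cy3 and triangles for the mutant in Cy5, and black bars give the mean ± SD of 3 replicates. The 24 means run from -3.61 for fer3 to 3.30 for bkdA1.

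The number of calls depended on the replicates used. Without replicate 1, 2 or 3 the count of passing probes was 65, 1 or 5. With all 6 arrays and the replicate number as a block it was 78 (68 higher and 10 lower), of which 77 were among the 123, and with the mutant in Cy5 alone it was 69. A fit to a loop of 3 batches, chosen after the correlations between arrays were seen, gave the same means and 354 calls, of which 114 were among the 123. Averaging the arrays by shared deviations in place of numbers, also chosen afterwards, gave 3608 calls, of which 1624 were higher and 1984 lower. The arrays averaged there had deviations that correlated at -0.97, -0.91 and -0.94, so their spread cancels by construction and this count is no evidence of more changes. The loop fit is built from the same pairs of arrays.

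Among genes of nitrogen assimilation, 1 of 2 loci annotated as glnK, a gene for a PII signalling protein, was higher in the mutant. This locus, blr0606, was 2.48-fold higher at 1.31 ± 0.24 (SD, n = 3; limma, adjusted p = 0.00127). The other, blr0612, stood at -0.12 ± 0.65 and the ammonium transporter gene amtB (blr0613) at 0.14 ± 0.38. The PII gene glnB (blr4948) was at 0.70 ± 0.17 (limma, adjusted p = 0.463) and the glutamine synthetase gene glnII (blr4169) at -0.38 ± 0.45. The glutamine synthetase loci glnA (blr4835 and blr4949) were at -0.15 ± 0.59 and -0.15 ± 0.25, and the glutamate synthase genes gltB (blr7743) and gltD (blr7744) at 0.48 ± 0.36 and -0.05 ± 0.13. Of the 11 probes of this list 1 rose, both over all probes and adjusted over the list alone, and 10 did not pass. The list median was -0.09 and its mean 0.14, and the list as a whole did not pass (camera, adjusted p = 0.3).

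Of 7 probes of type III secretion, the apparatus that delivers proteins into host cells, 4 rose over all probes and 5 rose adjusted over the list alone. The 4 were rhcS (bsr1820, 1.36 ± 0.31), rhcR (blr1819, 1.22 ± 0.28), rhcQ (blr1818, 1.18 ± 0.39) and rhcC2 (bll1842, 0.98 ± 0.26), of which rhcC2 did not pass with the replicate block (limma, adjusted p = 0.058). The others, which did not pass, were rhcU (blr1822, 0.83 ± 0.17), rhcC1 (bll1811, 0.41 ± 0.41) and rhcN (blr1816, 0.16 ± 0.94). The list median was 0.98, with 1.02, 0.84 and 0.91 in replicates 1, 2 and 3. The list was higher than other probes (camera with a preset correlation, adjusted p = 1.95e-14). The correlation estimated among its members was 0.10, above the preset 0.01, so this p-value may be too small. The call was lost with an estimated correlation, by which no list passed (camera, adjusted p = 0.268). By fry, which tests the list against no change rather than against other probes, it did not pass for a change in 1 direction (adjusted p = 0.153) and passed for changes in either direction (adjusted p = 0.0293).

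Of 25 nodulation probes, 5 rose, both over all probes and adjusted over the list alone, and 20 did not pass. The 5 were nolB (blr1812, 1.88 ± 0.20), nolU (blr1814, 1.53 ± 0.35), nolV (blr1815, 1.33 ± 0.53), nodD2 (bll2021, 1.25 ± 0.65) and nolA (bll2019, 1.23 ± 0.83). With the replicate block nolV, nodD2 and nolA did not pass (limma, adjusted p = 0.0511, 0.331 and 0.310). As background, nolB, nolU and nolV belong to the type III secretion gene cluster, and nodD2 and nolA encode regulators of nodulation genes. The list median was -0.07 while its mean was 0.24, so the median and the test differ in sign. Its rise passed with a preset correlation (camera, adjusted p = 0.0015) and was lost with an estimated correlation (adjusted p = 0.308 with an estimated correlation). The estimated correlation was -0.012, below the preset 0.01, so correlation between members does not account for this loss. The rise was also lost without replicate 2 (camera, adjusted p = 0.157) and with the loop fit (adjusted p = 0.336).

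Of 33 probes of chaperones and heat shock proteins, none passed over all probes by limma and 2 fell adjusted over the list alone, with 29 below 0. The chaperonin genes groEL (bll2059, -0.87 ± 0.67), groES (blr6978, -0.86 ± 0.53), groES (blr5226, -0.81 ± 0.45) and groEL (blr5626, -0.64 ± 0.15) had the smallest p. The list median was -0.19. The list was lower than other probes with a preset correlation (camera, adjusted p = 2.92e-05), and the call was lost with an estimated correlation (adjusted p = 0.268 with an estimated correlation).

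No member of the other 12 lists except glnK blr0606 passed over all probes, and none of these lists passed as a whole (camera, smallest adjusted p = 0.113). Denitrification (16 probes) had a median of -0.12, with norD (blr3217) at -0.31 ± 0.25 and napC (blr7040) at -0.27 ± 0.50. Assimilatory nitrate and nitrite use (10 probes) had a median of -0.04, with nasA (blr2809) at -0.22 ± 0.32 and nrtC (blr2805) at -0.21 ± 0.73. Urea, amide and purine nitrogen catabolism (8 probes) had a median of -0.06, with ureG (blr1460) at 0.28 ± 0.68 and atzD (blr7281) at -0.28 ± 0.62. Genes of nitrogen fixation (22 probes) had a median of -0.13, with fixK (bll2757) at 0.66 ± 0.13 (limma, adjusted p = 0.595) and nifS (blr4338) at 0.40 ± 0.15. That list also counts nifR (blr4486) of the ntr region, at -0.61 ± 0.43, with a smaller p than nifS. Low-oxygen respiration (9 probes) had a median of 0.03, with fixJ (bll2759) at 0.16 ± 0.74 and fixI (blr2769) at -0.15 ± 0.15. This list was also meant to hold fixK2, but no tested probe carried that symbol. The gene may still have been measured under the symbol fixK. Probes with the symbol fixK, bll2757 among them, were counted only with nitrogen fixation.

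Uptake hydrogenase and carbon fixation (40 probes) had a median of -0.08, with hoxX (bll6926) at -0.32 ± 0.38 and hypA (bll6932) at -0.27 ± 0.42. Flagella and chemotaxis (63 probes) had a median of 0.03, with cheY (blr2342) at 0.71 ± 0.14 (limma, adjusted p = 0.404) and cheA (blr2343) at 0.41 ± 0.18. Ribosomal proteins (52 probes) had a median of 0.10, with rpsG (bll5404) at 0.40 ± 0.13. ATP synthase and respiratory complex I (21 probes) had a median of 0.13, with nuoF (bll4912) at 0.49 ± 0.33. Iron and heme uptake (10 probes) had a median of -0.01, with exbB (bll7073) at -0.24 ± 0.10. Sigma factors (7 probes) had a median of -0.14, with rpoH2 (blr7337) at 0.64 ± 0.37 (limma, adjusted p = 0.689).

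**Figure D3:**
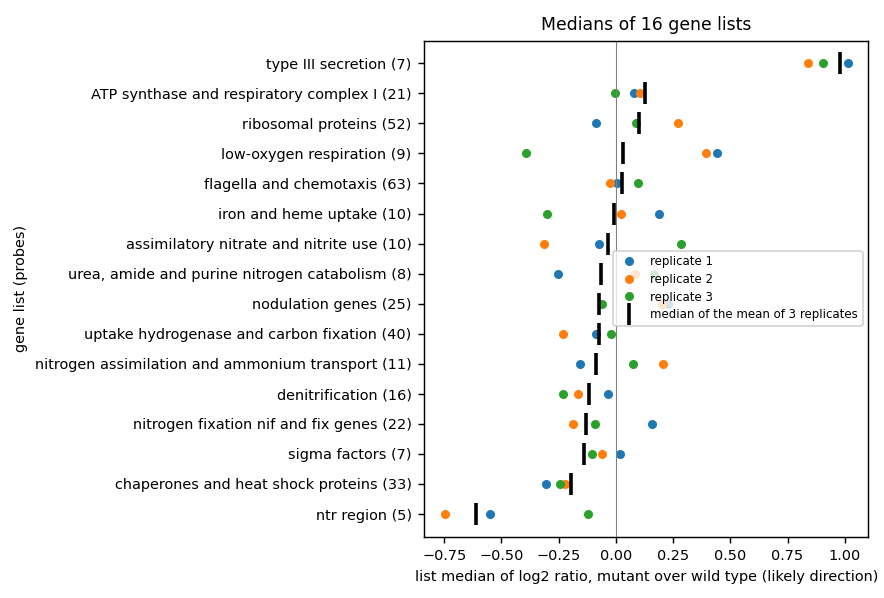
Median log2 ratio of mutant over wild type for 16 gene lists, with the number of probes in brackets. Coloured points are the medians in replicates 1, 2 and 3 and black ticks the median of the 3-replicate means, from -0.61 for the ntr region to 0.98 for type III secretion.

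Fold changes of genes next to each other were related. Across 4752 pairs of genes with consecutive locus numbers on the same strand, the log2 ratios had r = 0.45 (permutation p = 0.0001, the smallest that 10000 resamples can give). Across 2300 pairs on opposite strands r was 0.14 (permutation p = 0.0001, the smallest possible), and the difference of 0.31 had a permutation p of 0.0001, again the smallest possible. These are correlations across genes, which are not independent replicates.

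**Figure D4:**
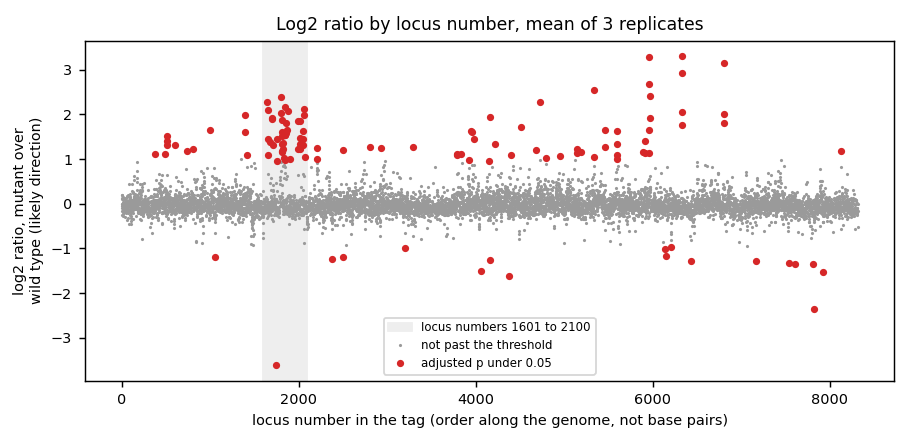
Mean log2 ratio of mutant over wild type (vertical axis) by the number in the locus tag (horizontal axis, order along the genome and not base pairs), with probes past the threshold in red. Of 395 tested genes with numbers from 1601 to 2100 (grey band) 43 passed, against 79 of 7232 elsewhere.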

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

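The loop fit and the pairing by shared deviations were chosen only after the data were seen. The 123 calls stayed within 1.5 times that count, between 107 and 150, with centring, scaling, quantile normalization, independent arrays, the Cy3 arrays alone, incomplete probes, the swap limit, robust variances, adjusted p under 0.1, the 2-fold limit and averaged probes. With treat at 1.2-fold it was 82, with 11 lower. With the replicate block, which keeps the pairing, it was 78 (68 higher, 10 lower), with a dye term 61 (53 and 8), and with the mutant in Cy5 alone 69 (58 and 11). Unadjusted p under 0.05 gave 335 (250 and 85). Leaving out replicates gave 1 to 65 calls, 0 to 58 higher and 1 to 7 lower, with fewer samples by construction. The loop fit gave 354 (270 and 84), 114 of them shared with the 123, and the pairing by shared deviations 3608 (1624 and 1984), where the spread cancels by construction. Turning every sign gives 18 higher and 105 lower. The cause was not tested for the others.

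The ntrC ratio of -0.68 was -1.63 with the mutant in Cy3 alone (past the threshold), 0.27 with the mutant in Cy5 alone, and 0.68 with the sign turned. It passed at -0.68 with an unadjusted p under 0.05 and with the pairing by shared deviations. Of the 4 list calls, 0 held with an estimated correlation. None of the 16 lists passed by that version (camera, smallest adjusted p = 0.268), so it does not decide on single lists. By fry, which tests each list against no change and not against other probes, 0 of the lists passed for a change in 1 direction. For changes in either direction type III secretion, nodulation and chaperones passed (adjusted p = 0.0293 each).

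Over 21 settings, 0 of 689 values of the 33 passing named genes turned sign and 111 were no longer past the threshold. The absence of turned signs was largely fixed in advance and says little about robustness. All 33 had the same sign of mutant over wild type on every array. Leaving out a replicate or using the arrays of either dye orientation alone therefore could not turn it. The replicate block, robust variances, treat, the other thresholds and the loop fit keep the same means. Of 416 values of the 20 others, 9 turned sign. Besides ntrC these were glnK blr0612 (0.124 with the mutant in Cy5 alone), glnA blr4949 (0.0695 with the mutant in Cy3 alone), gltD blr7744 (0.0236 with the mutant in Cy5 alone) and 5 on leaving out a replicate. The ranges on leaving out a replicate were -0.0630 to 0.359 for ntrX, -0.317 to 0.259 for glnK blr0612, -0.0744 to 0.286 for amtB, -0.485 to 0.0734 for glnA blr4835 and -0.110 to 0.0211 for gltD.

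List means that turned sign on leaving out a replicate, none of them past the threshold, ranged from -0.192 to 0.0838 for nitrate and nitrite use, from -0.0942 to 0.124 for urea, amide and purine nitrogen and from -0.0963 to 0.0353 for nitrogen fixation. They ranged from -0.0894 to 0.225 for low-oxygen respiration and from -0.0905 to 0.166 for iron and heme uptake. Correlations of same-strand neighbours kept their sign in 6 alternatives, between 0.40 and 0.45. Ribosomal proteins passed without replicate 1 (limma camera, adjusted p = 0.0146) and with the loop fit (0.00259), as did ATP synthase and complex I with the loop fit (0.00158), all with the preset correlation. With an estimated correlation, by which no list passed, both loop calls were lost (camera, adjusted p = 0.630 each). The table holds no intensities, so what signal over background limits is unknown.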

Other observations

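The genes named in the next 2 paragraphs were chosen after their values were seen. So were the tests of the array structure and the stretch of locus numbers. The count over other splits of the arrays was planned. Directions below are those of the report.

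Of the 123 passing probes, 122 were distinct genes by locus tag, and 62 of these lay in 20 runs of 2 or more. A run joins calls of 1 sign with locus numbers at most 2 apart, so it can skip a locus that did not pass. The 4 genes from blr6331 to blr6334 (bkdA1, bkdA2, bkdB and lpdA), which encode the branched-chain 2-oxo acid dehydrogenase complex, had log2 ratios between 1.76 and 3.30. The succinate dehydrogenase genes sdhD (blr0513), sdhA (blr0514) and sdhB (blr0515) passed at 1.41 ± 0.34, 1.51 ± 0.33 and 1.32 ± 0.27 (SD, n = 3), while sdhC (blr0512) did not, at 0.65 ± 0.28 (limma, adjusted p = 0.631). The 6 genes from blr5962 to blr5967 lay between 1.13 and 3.29. With the replicate block, blr5964 and blr5965 did not pass (limma, adjusted p = 0.348 and 0.310), and blr5964 did not have 1 sign on all 6 arrays.

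The fall of fer3 (bsr1750) stood alone among its neighbours. The nearest tested probes, bsr1749 and bll1751, were at 0.12 ± 0.24 and -0.16 ± 0.32. The 2 probes of blr1752 were both higher in the mutant, at 1.46 ± 0.65 and 0.96 ± 0.23.

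The arrays were related in a ring that the labels alone do not describe. The 3 pairs A1 and B2, A2 and B3, and A3 and B1 correlated higher than arrays of the same orientation by a mean of 0.424 (mean r of 0.40 against -0.02), and every one of them lay above every same-orientation pair. Independent dye-swapped pairs of the same RNAs would not give this, since same-orientation arrays share the dye and the strain effect with 1 sign, while these 3 pairs share the strain effect with opposite signs and so would correlate no higher. An effect of slide or day shared by each of these pairs, independent between them, is argued against by the variance of the sum of the 3 shared components, which was 0.161 of the sum of their variances (0.142 to 0.189 over 200 resamples of probes), where independence gives about 1. A candidate explanation is that RNA of 3 batches was compared across batches in a cycle, since their contrasts then cancel, as that ratio of 0.161 shows, but the labels do not record it and it was found in the same data. Under it the mean fold changes stay as reported, the median SD falls from 0.41 over replicates to 0.13 over the inferred batches, and 354 probes pass, among them glnB (limma, adjusted p = 0.00865) and ntrY (adjusted p = 0.00455). The loop values are built from the same 3 pairs, whose spread cancels, so this smaller SD and these calls are no separate support for it. Under the loop the 3 numbered replicates would also share samples. The SDs with n = 3, the main p-values and the probes that did not pass would then not hold as stated.

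Of the 10 splits of the 6 arrays into 3 and 3, 2 gave at least as many calls as the real one, the real one included. The real count was 123 and the highest other 575, and with 10 splits a share under 0.05 cannot be reached. The 575 came from A1, B1 and B2 against A2, A3 and B3, which parts 1 replicate number, and such a number points to a structure of the arrays other than the strains. The 3 other splits that part all 3 numbers gave 0 calls.

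Calls were concentrated in 1 stretch of locus numbers, from 1601 to 2100, which by their symbols includes genes of nodulation, nitrogen fixation and type III secretion. There 43 of 395 tested genes passed (10.9%), 42 of them higher, against 79 of 7232 elsewhere (1.09%). The 4 type III secretion probes and the 5 nodulation probes that rose all lie in it. Those list results and this concentration are therefore not separate findings. No probe of the nitrogen fixation list passed. The runs of nearby loci, which can hold genes of both strands, were placed at random in a test. None of 10000 placements put as many calls into any stretch of that many genes (permutation p = 0.0001, the smallest they can give). The highest placement held 35. The median log2 ratio of all tested genes of the stretch was -0.0492 (quartiles -0.15 and 0.10). This does not decide on a copy number change of the whole stretch, because signal over background is unknown and probes without signal would show none. That the genotype acts on some genes of this stretch remains open and may be followed up as a hypothesis, as does a difference in history between the strains, and neither was tested.

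The deposited ntrC ratio was negative on all 6 arrays, though only -0.002 on B3. Before turning, 57 of 7800 probes (0.731%) had 1 sign on all 6 arrays. The mean of ntrC before turning was -0.95, where the SD over probes was 0.11, and only 0.103% of probes had a mean at least as large in size. In a dye swap, the mean before turning follows the dye and not the strain. For ntrC this part was larger in size than the mean of mutant over wild type, -0.68. What gives this probe such a dye part was not tested.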
